A study of Homo sapiens with 12 samples.

How the data were processed

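NCI-H292 is a human lung mucoepidermoid carcinoma line. The submitters compared a control derivative (pcDNA) with cells stably overexpressing heme oxygenase-1 (pcHO1), each left untreated (naive) or given tumour necrosis factor (TNF, 30 ng per ml in the labels' treatment protocol, whereas the series design text gives this figure per ul) for 24 hours in serum-free medium. The 4 groups held 3 arrays each, 12 in all. Per the labels, total RNA was labelled with Cy3 and each replicate number came from an independent experiment with its own batch of cells. The 12 arrays lay on 3 slides of 4 arrays, per the file headers, and each slide carried 1 array of every group with the same replicate number, so that slide and experiment are one and the same factor.

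The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 9.5.1.1, per the file headers. Within each array that program subtracted a spatially detrended background and corrected a multiplicative trend, per the file headers, and nothing was scaled between arrays. The processed intensity was used, with the program's flags for outlier spots and its call of whether a spot was well above background. The deposited value table holds log2 values. Its normalization is not stated, and the values themselves show equal quantiles in every column. Columns were matched to scanner files by rank correlation: 11 of the 12 matched the file of the same sample, and the column of TNF-treated pcHO1 replicate 2 did not. All comparisons therefore used the scanner files, and the value table served only as an alternative. No per-sample column was left unread.

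The processed intensity was log2-transformed here and the 75th percentile of each array was subtracted. Control spots and outlier spots were left out and repeated spots of a probe were averaged. The array held 45015 spots, of which 43376 were not controls, for 41000 probes. Probes were named through the RefSeq gene table by accession (23958), by current symbol (2755) or by synonym (1032), and 13255 kept the name in the file. Probe coordinates are those in the files, on hg18. A probe was kept when it was well above background on all 3 arrays of at least 1 group and had at least 2 values in each group, and each gene was represented by its probe with the highest mean, which left 19603 genes.

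Expression was modelled with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the 4 groups, 8 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. The comparisons were pcHO1 minus pcDNA in naive cells, the same in TNF-treated cells, the average of both, TNF minus naive in each line, and the difference between the lines' responses to TNF (the interaction). On data simulated from these arrays for the naive comparison (18115 genes, 200 changed), 5.5% of genes changed by 1 log2 unit were recovered with 0 false calls, 67% of those changed by 2 units with 10 false calls, and 95% of those changed by 4 units with 11 false calls. The simulated noise was drawn independently for each gene and array, with no effect of experiment or slide. These shares may therefore not carry over to the real arrays. The number of arrays limits the precision.

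Before the data were examined, 29 lists of pathways, responses and cell type markers, the tests, most of the alternatives and the rule for naming genes were fixed. Lists with at least 5 measured genes, 27 of them, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. Some lists share members, so that their results are not independent. LTB stands in the NF-kB and cytokine lists, CXCL8 in the NF-kB and angiogenesis lists and IER3 in the EGFR and NF-kB lists. Camera with an estimated correlation, and fry, were run beside it. HMOX1 is named in every comparison. The other genes named are the 10 largest rises and 10 largest falls among those past the threshold whose groups did not overlap, and up to 4 members of each described list with the smallest p, except that some members are withheld and not reported. Where fewer than 5 genes passed in a direction, the 5 with the smallest p are given as values that did not pass. A fold is printed as "at least" where a gene was well above background on no array of the lower group: that group's values below the lowest normalized signal that was well above background on the same array were raised to it. No fold is given where both groups were in that state.

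The replicate numbers pair the arrays, because the labels tie a number to an experiment with its own cells and the headers tie it to a slide. Deviations from the group means correlated between naive and TNF-treated arrays of the same number (0.46 to 0.563 in pcDNA, 0.286 to 0.345 in pcHO1). Between the lines they correlated at 0.192 to 0.415 with TNF and at -0.0731 to 0.286 without. A fit with the replicate number as a block (6 residual degrees of freedom) was also run.

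The alternatives were other filters on dim probes, quantile normalization, median centring, normexp background correction (offset 50) with either scaling, a trended and robust variance, the replicate block, only the arrays compared, other handling of a gene's probes and of outlier spots, a minimum log2 change of 1, the value table, and leaving out each array. Chosen after the data were seen were the value table with its mismatched column, quantile normalization with the block, and the fit without 3 arrays of unusual background or signal range. That last fit left 1 naive pcDNA array, so that its changes are given without counts of genes. Chance was examined by regrouping the arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.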

Results

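Whole-genome expression was measured on 12 one-colour arrays of NCI-H292 cells: 3 of untreated pcDNA cells, 3 of pcDNA cells given TNF, 3 of untreated pcHO1 cells and 3 of pcHO1 cells given TNF. Heme oxygenase-1 (HO-1, gene HMOX1) breaks heme down into biliverdin, iron and carbon monoxide. The series asks how its overexpression changes genes of inflammation, blood vessel growth, proliferation, cell death and adhesion. The 75th percentile of the signal lay between 521 and 1142 units per array, and 47.2% to 86.1% of spots were well above background. The arrays of naive pcDNA replicates 1 and 3 had the fewest such spots (49.0% and 47.2%) and negative-control standard deviations of 14.29 and 13.83, against 3.889 to 7.529 on the other arrays. Naive pcHO1 replicate 1 had the most (86.1%). The first principal component held 40.1% of the variance and separated the lines. No pair of arrays was identical.

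HMOX1 was measured by 1 probe, spotted 10 times per array (chromosome 22, 34120122 to 34120181). Its normalized log2 signal was -1.996 ± 0.99 (SD, n = 3) in naive pcDNA, -1.94 ± 0.70 in pcDNA with TNF, -1.42 ± 0.56 in naive pcHO1 and -2.35 ± 0.82 in pcHO1 with TNF. The difference between the lines was 0.57 (SE 0.564, adjusted p = 0.528) in naive cells and -0.41 (adjusted p = 0.777) with TNF, and it averaged 0.08 (SE 0.399, adjusted p = 0.903). Within the 3 slides the naive difference was 1.29, 0.78 and -0.35. HMOX1 did not pass in any comparison. The labels do not say which part of the HMOX1 transcript the construct carries, so the probe cannot check the labels, and pcDNA and pcHO1 stand for the cells as labelled.

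In naive cells, ligands of the epidermal growth factor receptor (EGFR) and inflammatory mediators were among the genes lower in pcHO1 than in pcDNA. HBEGF, a membrane-anchored EGFR ligand (chromosome 5, 139693236 to 139693295), was lower 17.4-fold (log2 change -4.12, SE 0.245, n = 3 per group, adjusted p = 5.65e-06). AREG, the EGFR ligand amphiregulin, was lower 21.0-fold (-4.39, SE 0.566, adjusted p = 7.76e-04). The neutrophil chemokine CXCL8 was at least 14.4-fold lower (adjusted p = 2.39e-04) and the cytokine IL1B was 16.9-fold lower (SE 0.351, adjusted p = 5.8e-05). Among the genes that were higher, DEFB1, an antimicrobial beta-defensin, differed by 69.6-fold (6.12, SE 0.438, adjusted p = 2.01e-05). BPIFA1, a secreted airway defence protein, was higher by at least 39.3-fold and PPARGC1A, a coactivator of mitochondrial biogenesis, by 58.9-fold (5.88, SE 0.22, adjusted p = 4.78e-07). The other genes picked among the rises were MXRA5, a matrix-remodelling-associated protein, at least 20.6-fold higher, the transcription factor ATOH8 (at least 24.1-fold) and the Hedgehog-binding growth-arrest protein GAS1 (59.5-fold). They were joined by TMEM25 (at least 27.1-fold), the costimulatory ligand CD86 (54.8-fold), KANK4 (at least 11.1-fold) and the Wnt receptor FZD10 (47.6-fold). Those picked among the falls included DRC11, a component of motile cilia (74.3-fold, well above background on 1 of the 3 naive pcHO1 arrays), FGF13 (26.3-fold) and the ERK phosphatase DUSP6 (19.0-fold). Also lower were the collagenase MMP1 (17.0-fold), the ubiquitin ligase MARCHF4 (at least 3.96-fold) and INHBA, the activin A subunit (12.8-fold). Each of these 20 genes moved the same way on all 3 slides, which the rule for naming them fixed, since their groups could not overlap. They were picked by fitted change, which does not rank the genes given as bounds. GAS1, PPARGC1A, CD86 and FZD10 were well above background on 1 of the 3 naive pcDNA arrays, so that their folds rest partly on background-level signal.

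Of 30 measured EGFR ligands and immediate targets, 14 were lower and 0 higher in naive pcHO1 cells (16 and 0 adjusted over the list alone), among them TGFA, a further ligand (-2.29), and IER3, an immediate early gene (-2.28). The list's median lay at -1.16 relative to all genes (camera adjusted p = 3.2e-10), a call lost with the estimated inter-gene correlation (adjusted p = 0.0574 with an estimated correlation). Of 40 TNF and NF-kB targets, 16 were lower and 1 higher (18 and 1 adjusted over the list alone), including IL1A by 12.4-fold. The median was -0.89 relative to all genes (adjusted p = 3.2e-10, and adjusted p = 0.0459 with an estimated correlation). Among 36 cytokines and chemokines 12 were lower and 2 higher (12 and 4 adjusted over the list alone), with the lymphotoxin gene LTB lower 7.24-fold. This list lay at -0.85 relative to all genes (adjusted p = 5.36e-05, adjusted p = 0.11 with an estimated correlation). Of 37 genes of angiogenesis 7 were lower and 1 higher (9 and 2 adjusted over the list alone), with PLAU and PLAUR, urokinase and its receptor, at -2.48 and -2.40 and the chemokine receptor CXCR4 at least 3.31-fold lower. Relative to all genes it lay at -0.41 (adjusted p = 0.00157, adjusted p = 0.0824 with an estimated correlation). The raw medians within slides 1, 2 and 3 were -0.80, -1.10 and -1.23 for the EGFR list, -0.55, -0.77 and -1.02 for NF-kB targets, -0.28, -0.67 and -1.29 for cytokines, and -0.36, -0.19 and -0.24 for angiogenesis.

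Of 43 cell adhesion genes 9 were lower and 3 higher (11 and 5 adjusted over the list alone), with the integrin ITGA2 at -1.67, the mesenchymal cadherin CDH11 at least 2.09-fold higher, the galectin LGALS1 at -2.10 and the protocadherin PCDH7 at 3.04. The relative median was -0.43 (adjusted p = 0.00933, adjusted p = 0.0702 with an estimated correlation). Matrix and protease genes went both ways, 10 lower and 6 higher of 40 (12 and 8 adjusted over the list alone). The collagens COL5A1, COL6A1 and COL12A1 were higher by 32.0-fold, 12.2-fold and 6.8-fold, and tissue plasminogen activator PLAT was lower 7.83-fold. COL5A1 and COL6A1 were well above background on 1 of the 3 naive pcDNA arrays. The matrix list lay at -0.34 (adjusted p = 0.0383, adjusted p = 0.11 with an estimated correlation). Tight junction genes (4 of 18 lower, none higher, 5 adjusted over the list alone; CLDN1 -1.14, CLDN23 -1.06) had a relative median of -0.50 (adjusted p = 0.0432, adjusted p = 0.246 with an estimated correlation). Hypoxia and glycolysis genes (6 of 34 lower, 7 adjusted over the list alone; the stress gene NDRG1 -1.88) lay at -0.35 (adjusted p = 0.00765, adjusted p = 0.692 with an estimated correlation). For p53 targets 7 of 29 were lower and 2 higher (7 and 3 adjusted over the list alone), with the stress cytokine GDF15 at -2.33 and the cell cycle inhibitor CDKN1A at -1.63. Their relative median was -0.19, and it turned to 0.04 after quantile normalization (adjusted p = 0.0261, adjusted p = 0.357 with an estimated correlation). None of 40 genes of G2 and mitosis passed alone, and the list lay at -0.52 (adjusted p = 0.00283, adjusted p = 0.692 with an estimated correlation). Markers of 2 other cell types were higher. Fibroblast markers (4 of 9 higher, 4 adjusted over the list alone; MFAP5 2.22, TAGLN 2.58, FBN1 1.63, COL1A1 1.18) had a relative median of 1.03 (adjusted p = 0.0193, adjusted p = 0.351 with an estimated correlation). Endothelial markers (2 of 8 higher, 5 adjusted over the list alone, VWF 1.21, CLDN5 2.72) had one of 0.92 (adjusted p = 0.0261, adjusted p = 0.417 with an estimated correlation). Their raw medians were 1.78, 0.29 and 1.13 on slides 1, 2 and 3. The list's deviation from its mean over the 12 arrays was 1.34, 0.328 and 0.323 in naive pcHO1 replicates 1, 2 and 3. In naive pcDNA it was -0.81, -0.0004 and -0.803. The 3 arrays of unusual background or signal range thus stood furthest apart.

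Apoptosis regulators did not shift as a list (adjusted p = 0.102), although 9 of 42 were lower and 5 higher (9 and 7 adjusted over the list alone). CFLAR, an inhibitor of death-receptor signalling, was lower 5.97-fold, as were the death receptors TNFRSF10B (-1.28) and FAS (-0.95), while the death-associated kinase DAPK1 was at least 2.59-fold higher. NRF2 targets, the oxidative stress response to which HMOX1 belongs, did not pass with camera either (adjusted p = 0.31), with 6 of 32 higher and 1 lower (7 and 3 adjusted over the list alone). Fry, which asks whether members differ at all and not whether they differ more than other genes, called them higher (adjusted p = 0.00744). The aldehyde dehydrogenase ALDH3A1 was at least 11.5-fold higher, and ABCC3 (1.60), PIR (1.90) and UGT1A6 (2.26) were higher. Genes of heme and iron handling had an adjusted p of 0.388 with camera and 0.012 with fry (higher, at a raw median of 0.14 beside 0.15 for all genes), with the heme synthesis enzyme ALAD (1.57) higher. Cancer-testis antigens and neuroendocrine markers had 4 measured genes each and were not tested.

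In all, 3024 of 19603 genes (15.4%) passed between the naive lines, 2071 higher and 953 lower in pcHO1, and 2939 of them had 1 sign on all 3 slides. The replicate block gave 4719 (3184 and 1535). The balance of directions differed with scaling, background correction and the choice of probes. With probes well above background on all 12 arrays 748 genes were higher and 825 lower. The median of all genes was 0.15 with the 75th percentile and -0.39 with median centring. The higher and lower calls were 1186 and 1040 after quantile normalization, 708 and 1832 with median centring, and 42 and 55 with normexp correction scaled to the 75th percentile. They were 992 and 1148 with normexp and quantiles and 1396 and 154 in the value table. With normexp and the 75th percentile 9 of the 20 genes (MXRA5, BPIFA1, ATOH8, TMEM25, CD86, KANK4, CXCL8, MMP1 and MARCHF4) lost their call. Quantile normalization ended the calls of the adhesion (0.135), endothelial (0.135), hypoxia (0.135), tight junction (0.138), p53 (0.154) and matrix (0.289) lists. The count was 1533 without naive pcDNA replicate 3 and 1720 without replicate 1 of that group. Leaving out both and naive pcHO1 replicate 1 left 1 naive pcDNA array, so that no count is given for that fit. MARCHF4 stood at -4.32 and INHBA at -3.99 there.

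**Figure D1:**
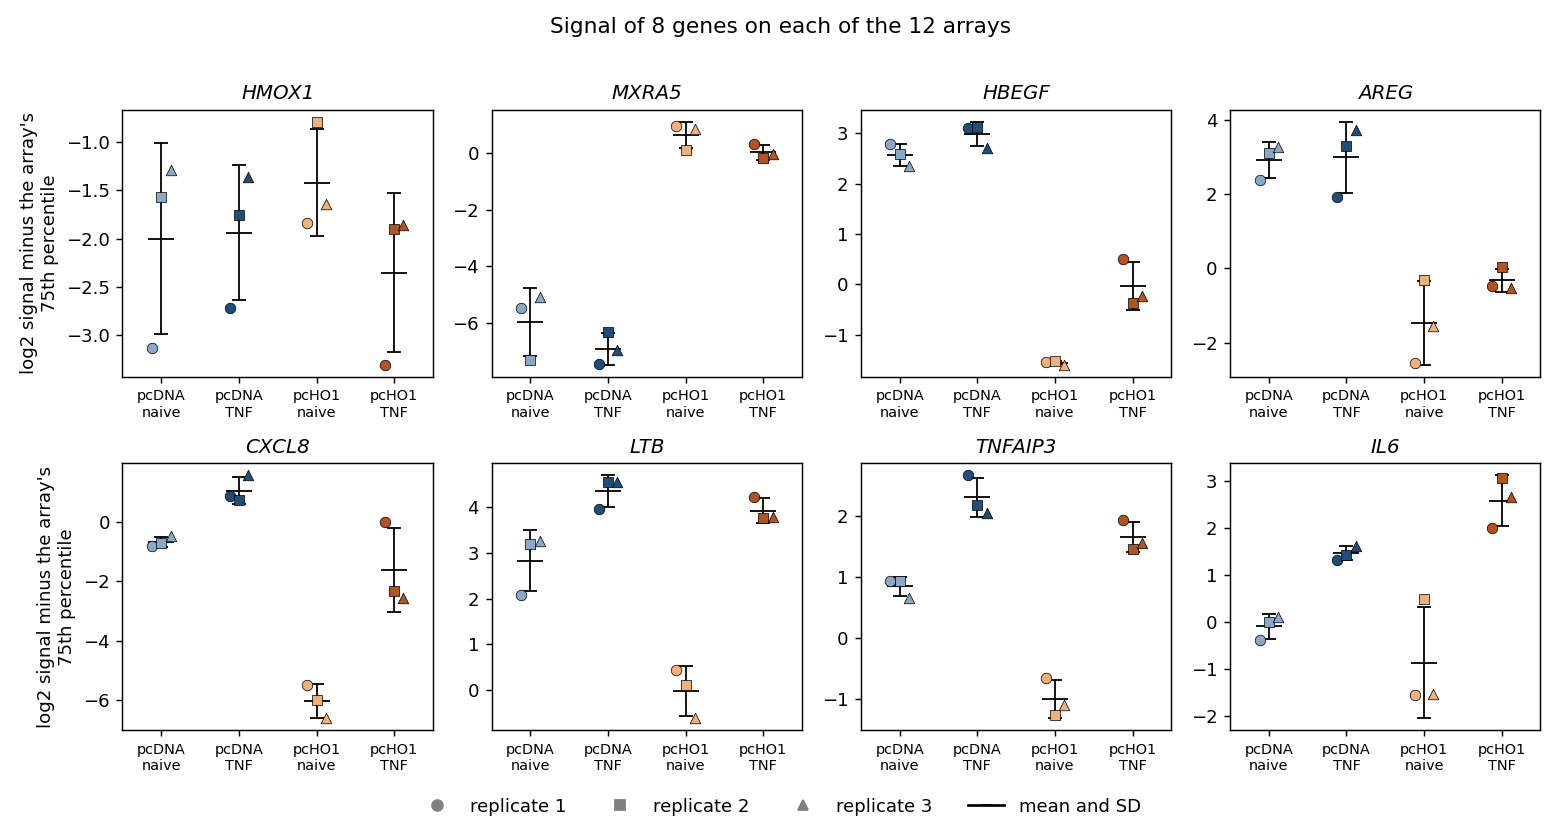
Signal of 8 genes on the 12 arrays, as log2 signal minus the array's 75th percentile; points are arrays marked by replicate and bars are means ± SD of 3. HBEGF and AREG lay lower and MXRA5 higher in pcHO1 with and without TNF, whereas HMOX1 overlapped between the lines.

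With TNF, the lines differed in many of the same genes. MXRA5 was at least 35.5-fold and TMEM25 at least 67.1-fold higher in pcHO1. BPIFA1 was 86.0-fold higher (2 pcHO1 arrays with values against 3 pcDNA arrays) and PPARGC1A 72.0-fold (6.17, SE 0.22, n = 3 per group, adjusted p = 2.84e-07). KANK4 was at least 15.8-fold and FZD10 43.4-fold higher. The synaptotagmin SYT12 was 81.4-fold higher (adjusted p = 8.1e-06), the endoplasmic reticulum peroxidase GPX7 at least 19.0-fold, the transcription factor RUNX3 at least 23.1-fold (adjusted p = 1.97e-06) and ZKSCAN7 at least 9.35-fold. FGF13 was at least 45.7-fold lower (adjusted p = 8.1e-06), DRC11 at least 35.4-fold, the chromatin protein HMGA2 36.0-fold (-5.17, SE 0.504, adjusted p = 1.53e-04), MMP1 19.0-fold and DUSP6 15.3-fold. Also lower were TSHZ3 (at least 7.46-fold), FOXA2, a transcription factor of endodermal epithelia (at least 6.24-fold, adjusted p = 0.00285), NEURL1 (16.8-fold), ACSS3 (at least 3.82-fold) and MARCHF4 (at least 4.51-fold, adjusted p = 0.0109). PPARGC1A was well above background on 1 of the 3 pcDNA arrays with TNF, and HMGA2 and NEURL1 on 1 of the 3 pcHO1 arrays with TNF. HMGA2 and GPX7 each had 1 further probe, of the same sign, which did not pass. Of 2 further FOXA2 probes, both of the same sign, 1 passed.

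EGFR ligands and targets were again lower, 13 of 30 with none higher (16 and 0 adjusted over the list alone; HBEGF 8.03-fold, TGFA -2.28, the phosphatase DUSP1 -1.72). Their relative median was -1.16 (adjusted p = 8.4e-09, adjusted p = 0.159 with an estimated correlation). Angiogenesis genes (7 of 37 lower and 0 higher, 9 and 0 adjusted over the list alone) lay at -0.31 (adjusted p = 0.0026, adjusted p = 0.196 with an estimated correlation). PLAU was at -2.65, CXCR4 at least 3.63-fold lower and CXCL8 6.46-fold lower. Of 40 NF-kB targets 8 were lower and 2 higher (12 and 4 adjusted over the list alone), with IL1B lower 9.9-fold, IL1A at -2.10 and the chemokine CXCL2 at -2.48. The median was -0.36 relative to all genes (adjusted p = 0.00995, adjusted p = 0.305 with an estimated correlation). Within slides 1, 2 and 3 the raw medians were -0.81, -1.32 and -1.55 for the EGFR list, -0.66, -0.22 and -0.47 for angiogenesis and -0.35, -0.22 and -0.33 for NF-kB targets.

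Interferon-stimulated genes lay at 1.38 relative to all genes (adjusted p = 9.79e-06, adjusted p = 0.51 with an estimated correlation), though 2 of 43 passed alone (2 adjusted over the list alone): the antiviral proteins DDX60 (1.84) and SAMD9L (1.59). Their raw median was 0.44 on slide 1 and 1.93 and 1.83 on slides 2 and 3. Complement and acute phase genes (4 of 20 higher, 7 adjusted over the list alone) lay at 0.81 (adjusted p = 0.0026, adjusted p = 0.51 with an estimated correlation). The proteases C1S (2.62), C1R (1.72) and CFI (1.65) and the copper carrier CP (3.81) were higher. Fibroblast markers (2 of 9 higher, 4 adjusted over the list alone; MFAP5 2.45, TAGLN 2.05) lay at 0.88 (adjusted p = 0.00332, adjusted p = 0.305 with an estimated correlation). Squamous genes (4 of 27 higher, 4 adjusted over the list alone) lay at 0.50 (adjusted p = 0.0105, adjusted p = 0.51 with an estimated correlation). The keratins KRT17 (1.91), KRT14 (1.71) and KRT16 (1.83) and transglutaminase TGM1 were higher. Heme and iron genes had an adjusted p of 0.0503 with camera and 0.00519 with fry, with the transferrin receptor TFRC (1.14) and the heme transporter SLC48A1 (1.02) higher. The NRF2 list had an adjusted p of 0.118 with camera and 0.0123 with fry, with AKR1C1, an aldo-keto reductase, at 3.39.

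Between the TNF-treated lines 1809 genes (9.23%) passed, 962 higher and 847 lower in pcHO1, 1755 of them with 1 sign on all 3 slides. The block gave 2870 (1566 and 1304). With the block the G2 and mitosis list (lower, adjusted p = 0.00969), MHC class I (0.00567), heme and iron (0.0361) and mucins (0.0361) passed too. The count was 203 with normexp and the 75th percentile, where GPX7, RUNX3, KANK4, ZKSCAN7, TSHZ3, FOXA2, ACSS3 and MARCHF4 lost their call and the median of all genes was 0.23. It was 905 with median centring, 1031 with no filter on dim probes and 132 in the value table without its mismatched column, where FOXA2 (0.22) and NEURL1 (0.079) did not pass. Without pcDNA TNF replicate 2 it was 837 and MARCHF4 did not pass (adjusted p = 0.0554), without replicate 3 of that group 1000, and without pcHO1 TNF replicates 2 and 3 in turn 1115 and 1038.

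Across genes, the line differences in naive and in TNF-treated cells correlated at Pearson's r = 0.72 (Spearman's rho 0.656; genes are not independent replicates), and at 0.367 with no filter on dim probes. The groups share no array but share experiments and slides: each slide's deviation from the mean line difference correlated between naive and TNF-treated cells at 0.0805, 0.191 and 0.246, values that involve no mean difference. Higher in both were 826 genes, against 102 for independent lists, and lower in both 595, against 41.2, with 0 called in opposite directions. Averaged over both treatments, MXRA5 (at least 27.1-fold), BPIFA1 (at least 58.2-fold), TMEM25 (at least 42.6-fold), PPARGC1A (65.2-fold, SE of the log2 change 0.155, adjusted p = 8.52e-09) and KANK4 (at least 13.2-fold) were higher. So were GAS1 (49.3-fold), SYT12 (46.6-fold), FZD10 (45.5-fold), DEFB1 (44.3-fold) and GPX7 (at least 11.4-fold). Lower were DRC11 (at least 51.3-fold), FGF13 (at least 34.6-fold), HMGA2 (19.8-fold), MMP1 (18.0-fold), DUSP6 (17.0-fold), CXCL8 (at least 9.64-fold), MARCHF4 (at least 4.23-fold), AREG (14.4-fold), NEURL1 (14.3-fold) and INHBA (13.7-fold). These too were picked by fitted change, which does not rank the genes given as bounds, and PPARGC1A was well above background on 1 of 3 arrays in each pcDNA group. Altogether 4631 genes passed (2607 higher, 2024 lower), 1863 of them by at least 1 log2 unit. The split was 1083 higher and 2655 lower with median centring and 459 and 555 with normexp and the 75th percentile.

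By this average, EGFR ligands and targets (17 of 30 lower, none higher, 18 and 1 adjusted over the list alone) lay at -1.28 relative to all genes (adjusted p = 8.72e-10, adjusted p = 0.0963 with an estimated correlation). NF-kB targets (18 lower and 4 higher of 40, 19 and 4 adjusted over the list alone) lay at -0.54 (adjusted p = 4.17e-06, adjusted p = 0.0963 with an estimated correlation). Angiogenesis genes (14 lower and 3 higher of 37, 16 and 4 adjusted over the list alone) lay at -0.36 (adjusted p = 0.0014, adjusted p = 0.0963 with an estimated correlation). Cytokines (12 lower and 4 higher of 36, 15 and 6 adjusted over the list alone) lay at -0.69 (adjusted p = 0.00211, adjusted p = 0.274 with an estimated correlation). Adhesion genes (11 lower and 5 higher of 43, 17 and 7 adjusted over the list alone) lay at -0.46 (adjusted p = 0.0254, adjusted p = 0.0986 with an estimated correlation). Mitotic genes PRC1 (-0.96), PTTG1 (-0.92) and TPX2 (-0.74) were lower, 3 of 40 (0 adjusted over the list alone). Their list lay at -0.41 (adjusted p = 0.0118, adjusted p = 0.715 with an estimated correlation). Interferon-stimulated genes (4 of 43 higher, 2 adjusted over the list alone), with the antiviral tetherin BST2 at 4.61, lay at 0.70 (adjusted p = 0.017, adjusted p = 0.715 with an estimated correlation). Their raw medians were 0.08, 1.43 and 1.34 on slides 1, 2 and 3, so that slide 1 lay near the median of all genes (0.0972). Fibroblast markers (4 of 9 higher, 5 adjusted over the list alone) lay at 0.93 (adjusted p = 0.0126, adjusted p = 0.319 with an estimated correlation). Of 42 apoptosis regulators 10 were lower and 5 higher (10 and 5 adjusted over the list alone), with CFLAR at -2.34 and cytochrome c, CYCS, at 1.19 (adjusted p = 0.2). The complement list, not past at an adjusted p of 0.127, passed with the block (0.0363), and quantile normalization ended the call of adhesion (0.123).

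In pcDNA cells TNF raised lists of its known targets, with no single gene past the threshold. TNFAIP3, the feedback inhibitor A20 (chromosome 6, 138245372 to 138245431), was 2.74-fold higher in value (1.46, SE 0.233, n = 3 per group). TNF itself stood at 1.38, LTB at 1.52, the adhesion molecule ICAM1 at 0.78 and the chemokines CXCL2 and CXCL3 at 1.37 and 1.19. As a list NF-kB targets rose by a median of 0.44 relative to all genes (adjusted p = 2.06e-22, and adjusted p = 0.00319 with an estimated correlation). None of the 40 passed alone, and 10 were higher adjusted over the list alone. Cytokines rose by 0.61 (adjusted p = 1.89e-11, and adjusted p = 0.0293 with an estimated correlation; 4 higher adjusted over the list alone). Matrix genes rose by 0.20 (adjusted p = 0.00262, and adjusted p = 0.0293 with an estimated correlation; none adjusted over the list alone). On slides 1, 2 and 3 the raw medians were 0.74, 0.42 and 0.57 for NF-kB targets, 0.83, 0.46 and 0.65 for cytokines and 0.33, 0.16 and 0.26 for matrix genes. Smaller shifts passed for S phase genes (-0.18, turning to 0.15 with normexp and the 75th percentile; adjusted p = 4.41e-05, adjusted p = 0.42 with an estimated correlation). They also passed for hypoxia genes (0.07, adjusted p = 0.0468, adjusted p = 0.928 with an estimated correlation) and mucins (-0.09, adjusted p = 0.0468, adjusted p = 0.594 with an estimated correlation). No gene of these 3 lists passed alone. Across the slides the raw medians were -0.26, 0.01 and -0.01 for S phase genes, 0.25, 0.14 and 0.11 for hypoxia genes and 0.16, -0.19 and -0.12 for mucins, so that S phase genes and mucins had no common sign. After quantile normalization the hypoxia (0.0915) and mucin (0.102) calls ended.

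By limma, 0 of 19603 genes passed for TNF in pcDNA cells, 448 had an unadjusted p under 0.05 (336 higher, 112 lower) and 1 passed with the block, KRT6B (adjusted p = 0.0358), named after its values were seen. The smallest p values among higher genes belonged to TNFAIP3 (adjusted p = 1, and 0.0817 with the block), BEX5 (0.98), TNF, ZBED2 (1.02) and the connexin GJB2 (1.11). Among lower genes they belonged to keratin KRT15 (-0.89) and to SHC3, RUNX3, ALDH3A1 and ZNF704. The last 4 were well above background on no pcDNA array, and no change is read from them. None of the 10 passed. Without naive pcDNA replicate 2 the count was 10 (1 higher, 9 lower), and normexp with quantile normalization called TNFAIP3 (1.15, adjusted p = 0.0449). The 448 genes with an unadjusted p under 0.05 became 280 to 980 with 1 array left out.

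In pcHO1 cells TNF raised 11 genes, 7 of them in the list of NF-kB targets. LTB, a membrane cytokine of the TNF family (chromosome 6, 31656448 to 31656507), rose 15.4-fold (3.94, SE 0.362, n = 3 per group, adjusted p = 0.00315) and TNFAIP3 6.31-fold (2.66, SE 0.233, adjusted p = 0.00315). The cytokine IL6 rose 10.9-fold (3.45, SE 0.484, adjusted p = 0.0386) and CXCL8 at least 7.38-fold (adjusted p = 0.0325). The mitochondrial superoxide dismutase SOD2 rose 5.04-fold (adjusted p = 0.027), TNF 4.48-fold (0.0349) and IL1A 3.92-fold (0.0349). Outside the NF-kB list, keratin KRT6B rose 12.6-fold (adjusted p = 0.0263), GJB2 4.06-fold (0.027) and the sugar transporter SLC2A6 4.42-fold (0.0458). The eleventh gene, FST, the activin-binding protein follistatin, was named after its values were seen (1.92, adjusted p = 0.0349). Each of the 10 named by the rule rose on all 3 slides, but that rule fixed this, since it took only genes whose groups did not overlap.

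Of 40 NF-kB targets 7 rose (24 adjusted over the list alone) and the list rose by a median of 0.91 relative to all genes (adjusted p = 4.73e-40, and adjusted p = 3.83e-04 with an estimated correlation). Its raw medians within slides were 0.99, 0.86 and 0.98. Cytokines (5 of 36 rose, 16 adjusted over the list alone) rose by 0.60 (adjusted p = 3.77e-18, and adjusted p = 0.00521 with an estimated correlation). The cytokine and NF-kB lists share members such as LTB, so that these rises are not separate results. Matrix genes rose by 0.40 (0 of 40 alone, 1 adjusted over the list alone, tenascin TNC at 1.27; adjusted p = 1.91e-06, and adjusted p = 0.00467 with an estimated correlation). Adhesion genes rose by 0.20 (0 of 43 alone, 1 adjusted over the list alone, ICAM1 at 1.09; adjusted p = 0.00219, and adjusted p = 0.0325 with an estimated correlation). A further 14 lists passed with the preset correlation and not with the estimated one. The largest rises among them were those of interferon-stimulated genes at 0.90 (0 of 43 alone; adjusted p = 3.23e-08, adjusted p = 0.414 with an estimated correlation) and complement at 0.62 (adjusted p = 1.25e-05, adjusted p = 0.384 with an estimated correlation). Hypoxia genes lay at 0.52 (adjusted p = 1.45e-13, adjusted p = 0.249 with an estimated correlation; the carbonic anhydrase CA12 at 3.07, which did not pass). MHC class I lay at 0.49 (adjusted p = 0.00144, adjusted p = 0.414 with an estimated correlation) and endothelial markers at -0.65 (adjusted p = 0.0229, adjusted p = 0.384 with an estimated correlation). The raw medians of endothelial markers were -1.17, -0.02 and -0.20 on slides 1, 2 and 3, so that most of the fall lay on slide 1. That slide held naive pcHO1 replicate 1, the array with the most spots well above background (86.1%).

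**Figure D2:**
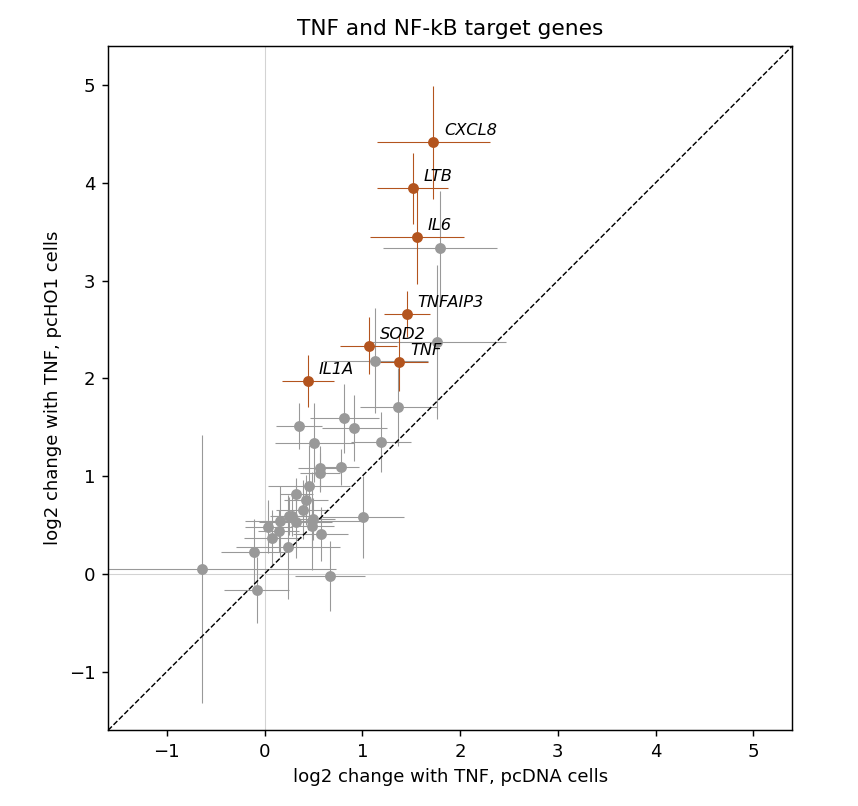
Log2 change with TNF of the 40 NF-kB targets in pcDNA cells (horizontal axis) against pcHO1 cells (vertical axis); bars are standard errors, the dashed line marks equal change and the 7 genes past the threshold in pcHO1 cells are labelled. The list's median change was 0.51 in pcDNA and 0.86 in pcHO1 cells.

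No gene fell past the threshold. The smallest p values among lower genes were those of CHCT1 (at least 4.33-fold lower in value, adjusted p = 0.0896), KRT15 (-1.21, 0.0896), the Rac activator TIAM2 (-1.75, 0.117), FGD3 (-0.97, 0.131) and CDH10 (-2.19, 0.142). TIAM2 and CDH10 were well above background on 1 of the 3 pcHO1 arrays with TNF. By limma, 1688 genes had an unadjusted p under 0.05 (464 higher, 1224 lower) and 45 passed with the block (43 higher, 2 lower). The 1688 became 974 to 2654 with 1 array left out and 169 with normexp and the 75th percentile. The 11 calls depended on single arrays, and LTB and TNFAIP3 alone kept theirs with each array left out. The count was 2 without pcHO1 TNF replicate 3 and 3 without pcHO1 TNF replicate 1. It lay at 4 or 5, all higher, without any 1 of the naive pcDNA arrays or of pcDNA TNF replicates 2 and 3. Leaving out some pcHO1 arrays turned most calls to falls: without pcHO1 TNF replicate 2 there were 2 higher and 4 lower, and without naive pcHO1 replicate 3 there were 2 higher and 6 lower, with 2 of the 11 genes kept in each case. Without naive pcHO1 replicate 1 there were 5 higher and 1 lower, and without replicate 2 of that group 5 higher and 3 lower. The count was 0 with only the 6 arrays compared and in the value table. With normexp and the 75th percentile, and with no filter on dim probes, 2 genes passed and 8 of the 10 named lost their call; with the former, CXCL8 stood at 0.78 and TNF at 0.80 (adjusted p = 1 for both). The count was 4 with the mean of a gene's probes, 25 with median centring (20 higher, 5 lower) and 20 with normexp and quantiles (16 higher, 4 lower). With the mean of a gene's probes 6 of the 10 named lost their call, among them TNF (1.155, adjusted p = 0.323) and TNFAIP3 (2.518, adjusted p = 0.0571). Quantile normalization ended the calls of IL6, SLC2A6, GJB2 and IL1A.

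The responses of both lines to TNF were compared directly through the interaction. NF-kB targets rose more in pcHO1 cells, by a median of 0.51 relative to all genes (camera adjusted p = 2.18e-14). The adjusted p was 0.0144 with an estimated correlation, and the raw median was 0.47 on each of the 3 slides. Chance cannot be excluded for this size: 5 of 100 groupings, the real one included, gave a size as large in either direction. With TNF the list still lay lower in pcHO1 than in pcDNA cells on every slide. Its median deviation from each gene's mean over all arrays was 0.446, 0.212 and 0.206 in pcHO1 with TNF. In pcDNA with TNF it was 0.716, 0.473 and 0.463 on the same slides. LTB (2.43), IL1A (1.53), TNFAIP3 (1.20) and IER3 (1.16) had the smallest p in the list, in which 4 genes passed adjusted over the list alone and 0 over all genes. The excess shrank to 0.05 relative to all genes with normexp and the 75th percentile. That setting moved the median of all genes in this comparison from -0.10 to 0.15, while with normexp and quantiles it was 0.0359. Fry gave an adjusted p of 0.0697 for the NF-kB list. Cytokines differed by 0.45 (adjusted p = 2.13e-06, adjusted p = 0.14 with an estimated correlation; 2 adjusted over the list alone) and interferon-stimulated genes by 1.03 (adjusted p = 3.33e-09, adjusted p = 0.422 with an estimated correlation).

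By limma, 0 genes passed for the interaction, 979 had an unadjusted p under 0.05 (85 higher, 894 lower) and 0 passed with the block. The 979 became 508 to 1641 with 1 array left out, 487 with quantile normalization and 138 with normexp and the 75th percentile. The smallest p values belonged to LTB, IL1A, NCOA7 (1.47), RUNX3 and PID1 among genes that responded more positively in pcHO1, and to TIAM2 (-1.96), SLC35G1 (-2.47), SLC22A13, TULP1 (-1.30) and PCDHB10 (-1.25) among the rest. None passed (adjusted p = 0.971). No change is read from RUNX3, PID1 and SLC22A13, which were well above background on no array of at least 1 of the 4 groups, and TIAM2, SLC35G1, TULP1 and PCDHB10 were so on 1 of 3 arrays in at least 1 group. Across all genes the responses of the lines did not correlate (Pearson's r = 0.0139, Spearman's rho -0.0338, genes not being independent replicates, and no array shared), while the 11 genes called in pcHO1 all had the same sign in pcDNA. Without pcHO1 TNF replicate 2 the interaction count was 3, and without naive pcHO1 replicate 3 it was 2.

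**Figure D3:**
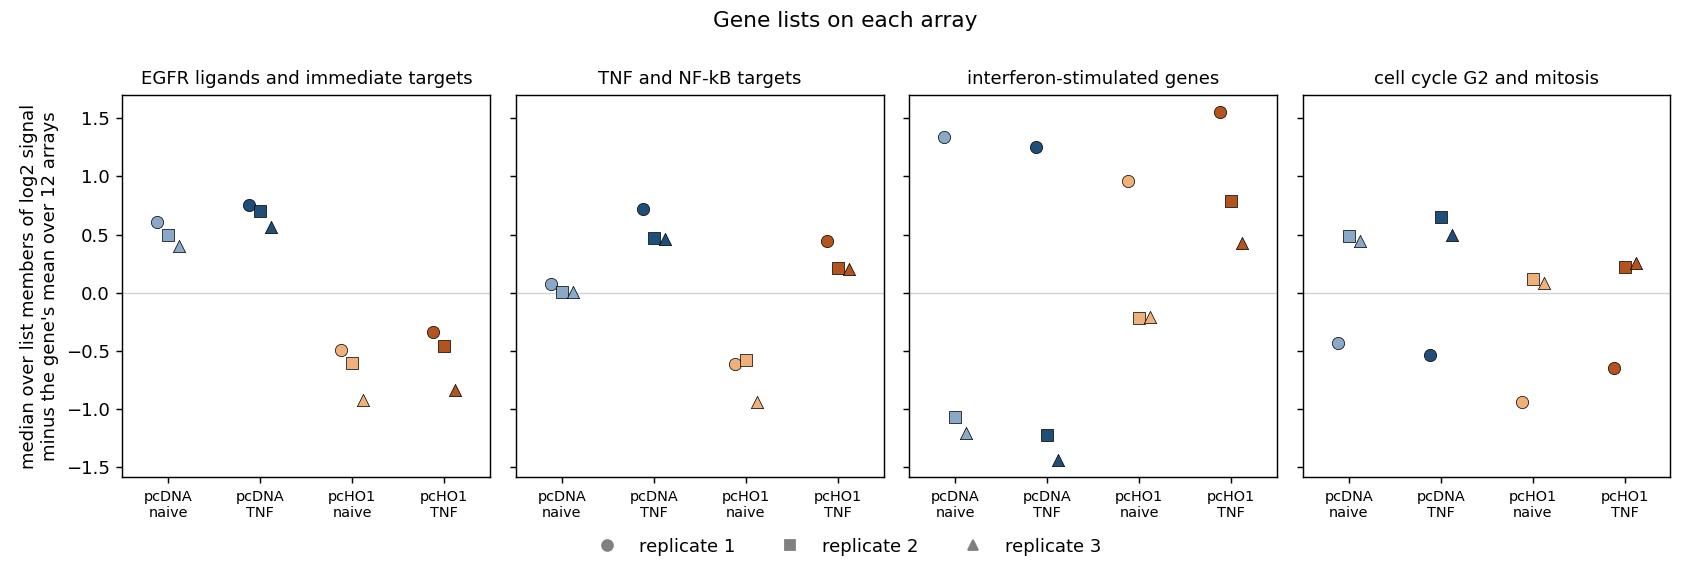
Median over each of 4 gene lists of log2 signal minus the gene's mean over the 12 arrays, with 1 point per array and replicates marked. EGFR targets lay lower in pcHO1, NF-kB targets lay higher with TNF, and replicate 1 lay highest in the interferon list within every group.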

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

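The tests for exchanged single arrays, for a probe that does not hybridise and for fibroblast RNA as the source of all the differences, and counting regroupings in either direction for the NF-kB list, were chosen after the results were seen. A test of the difference between the lines (the interaction) singled out 13 lists whose response to TNF was, relative to all genes (median difference -0.0958), more positive in pcHO1 than in pcDNA cells. Their median differences, before the median of all genes is taken off, were 0.41 for NF-kB targets, 0.934 for interferon-stimulated genes, 0.274 for hypoxia and glycolysis, 0.355 for cytokines, 0.8 for complement and 0.445 for MHC class I. They were 0.125 for G2 and mitosis, 0.135 for cholesterol synthesis, 0.0682 for cell adhesion, -0.00158 for EGFR ligands and targets, 0.0103 for p53 targets, 0.127 for the unfolded protein response and 0.129 for matrix genes. With an estimated correlation the NF-kB list alone kept its call. Relative to all genes, normexp with the 75th percentile turned the differences of adhesion (-0.12), mitosis (-0.11), the unfolded protein response (-0.11), matrix genes (-0.07) and p53 targets (-0.03) negative. Of 100 groupings of the arrays, the real one included and experiments not kept together, 5 gave at least as many lists (real value 13, highest other 13). Chance therefore cannot be excluded for the number of lists.

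HMOX1 was not measurably higher in the cells labelled as overexpressing it. A modest rise is not excluded, since the naive difference was 0.57 with an SE of 0.564. An exchange of single arrays between the lines is argued against, as 0 of the 12 arrays correlated better with the other line than with their own, while an exchange of all labels between the lines would not show in this test and stays open. A probe that does not hybridise is argued against, since 91.7% of the HMOX1 spots were well above background. On naive pcDNA replicate 1 this held for 2 of 10 spots. A transgene transcript that lacks the probe's target stays open, because the array holds 1 HMOX1 probe and the construct's extent is not stated. The possibility that the pcHO1 cells had lost the transgene's expression was not tested.

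The lines differed in 4631 genes on average. A chance division of these arrays is argued against: 1 of 100 groupings, the real one, gave as many (highest other 265). Experiments were not kept together, and most other groupings mix the lines, whose difference then adds to the spread and lowers their counts. Chance divergence of a line cannot be excluded this way, since each label stands for 1 derived line. Unequal detection as the source is argued against, since 23.3% of the genes well above background on all 12 arrays passed, against 24.2% of the rest. Unequal background stays open, because the test asks only whether genes were detected. The average gave 1014 genes with normexp and the 75th percentile and 4059 with normexp and quantiles. Without the 3 arrays of unusual background or signal range no count is given, since 1 naive pcDNA array is left. RNA of fibroblasts as the source of all the differences is argued against, since 4 of the abundant fibroblast transcripts COL1A1, COL1A2, COL3A1, DCN and LUM were well above background on fewer than 3 of the 6 pcHO1 arrays (COL1A1 on 6, COL1A2 and COL3A1 on 2, DCN on 1, LUM on 0). A small share of fibroblast RNA stays open. To argue against it, at least 3 of the 5 had to be well above background on no pcHO1 array, and only 1 (LUM) was. Of the 9 measured fibroblast markers all 9 were well above background on some pcDNA array and 1 stands in another list. HO-1 itself and differences between lines that were selected and grown apart cannot be told apart in this design, and neither was tested.

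The NF-kB response to TNF was stronger in pcHO1 cells (0.41), but chance cannot be excluded for the list's median relative to all genes: 5 of 100 groupings, the real one included and experiments not kept together, gave as large a size in either direction and 4 in the same direction (real value 0.52, highest other 0.605). An effect of 1 slide is argued against, as the lowest of the 3 slides gave 0.465. Compression of bright pcDNA spots stays open, since the dimmer members gave 0.354 (SE 0.215) with 0 saturated. A lower starting level in pcHO1 cells may contribute and stays open, because members lower in naive pcHO1 cells tended to respond more, at Spearman's rho -0.296 across members, but all genes gave -0.25. The size depends on the processing, and relative to all genes it was 0.05 with normexp and the 75th percentile.

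For each comparison of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. Between the naive lines the real value was 3024 genes and the highest other 0, and for lists 12 and 11; in each case 1 split, the real one, gave as many. With TNF they were 1809 genes and 0 (1 split), and 7 lists and 12 (6 splits). For TNF in pcHO1 cells they were 11 genes and 0 (1 split), and 18 lists and 16 (1 split). For TNF in pcDNA cells, by the unadjusted p, they were 448 and 2859 genes (7 splits), and 6 lists and 10 (5 splits). Of those 10 splits 4 part every pair of arrays of the same experiment, and among them the highest other was 244, while the splits that set experiments against each other reached 2859, which points to a structure by experiment. For lists, the other splits that part every pair gave 2, 3 and 0, against the real 6. For the number of lists in the average difference, 37 of 100 groupings gave as many (8, highest other 15), and for interaction genes with an unadjusted p under 0.05, among the 18115 with values on all arrays, 35 of 100 did (933, highest other 5516). Experiments were not kept together in these groupings. Chance cannot be excluded for either number, and the high value of the other groupings again points to structure among the arrays.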

How the results depend on the processing

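The value table with its mismatched column, the fit without 3 arrays of unusual background or signal range and quantile normalization with the block were chosen after the results were seen. Signal over background limits the results, since 47.2% to 86.1% of spots were well above it and another background correction or filter on dim probes moved the counts. Keeping outlier spots, or testing all probes, changed no count of genes by over 1.5 times. Where a count or direction changed below, the cause was not tested. The slide and the replicate number are 1 factor here, so that no separate slide block was run.

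With no filter on dim probes 1536 genes passed between the naive lines, 1031 between the TNF-treated lines and 2 for TNF in pcHO1, and the line differences in both treatments correlated at 0.367. Among probes well above background on all 12 arrays the counts were 1573 between naive lines and 20 for TNF in pcHO1, with fewer genes tested. Requiring a log2 change of 1 left 1863 in the average. Median centring gave 905 between TNF-treated lines and 25 for TNF in pcHO1. Normexp with the 75th percentile gave 97 between naive lines, 203 between TNF-treated lines, 2 for TNF in pcHO1 and 1014 in the average. Normexp with quantiles gave 1 gene for TNF in pcDNA and 20 in pcHO1. A trended robust variance gave 19 for TNF in pcHO1, and the mean of a gene's probes gave 4. With only the arrays compared, 1147 passed between naive lines and 0 for TNF in pcHO1. The value table without its mismatched column gave 1550, 132, 0 for TNF in pcHO1 and 1567 in the average, and with all 12 columns 652, 22, 0 and 561. Without the 3 arrays 466 passed between naive lines, 1 for TNF in pcDNA, 5 in pcHO1, 2744 in the average and 1 for the interaction. Quantile normalization with the replicate block gave 24 for TNF in pcHO1.

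The replicate block raised the counts to 4719 between naive lines, 2870 between TNF-treated lines, 1 for TNF in pcDNA and 45 in pcHO1. Of the first count's genes 3015 were among the 3024, and 1805, 11 and 4619 were shared for the TNF-treated lines, TNF in pcHO1 and the average. Lists past the threshold were 11 between TNF-treated lines with the block. The block also passed interferon-stimulated genes for TNF in pcDNA (0.0187, lower), mucins (0.0136) and squamous genes (0.0263) for the interaction, and lost metallothioneins for TNF in pcHO1 (0.0708). Beyond these and the calls given beside the results, it changed no other list call.

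With an estimated correlation the lists past the threshold numbered 1 between naive lines, 0 between TNF-treated lines, 3 for TNF in pcDNA, 4 in pcHO1, 0 in the average and 1 for the interaction, against 12, 7, 6, 18, 8 and 13. Fry gave 11 between naive lines, 8 between TNF-treated lines, 3 for TNF in pcDNA, 3 in pcHO1, 12 in the average and 0 for the interaction. It did not call mitosis, hypoxia and matrix genes between naive lines, interferon-stimulated, complement and squamous genes between TNF-treated lines, or mitosis and interferon-stimulated genes in the average. Quantile normalization gave 6 lists between naive lines, 11 between TNF-treated lines, 9 for TNF in pcHO1 and 6 for the interaction, and normexp with quantiles 5, 11, 10 and 6.

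HMOX1 passed nowhere and its sign changed. For TNF in pcDNA it was -0.0105 with quantile normalization, with and without the block, -0.0175 with median centring, -0.252 with normexp and the 75th percentile, -0.0279 with normexp and quantiles and -0.372 without the 3 arrays. In the average it was -0.183 with quantiles, with and without the block, -0.219 with median centring, -0.0698 with normexp and quantiles, -0.18 in the value table with all columns and -0.0275 without the 3 arrays. Between TNF-treated lines it was 0.222 with normexp and the 75th percentile. Among named genes, none of which had passed, signs changed with normexp and the 75th percentile for BEX5 in pcDNA (-0.519) and, in the interaction, for SLC35G1 (0.038), SLC22A13 (0.459), TULP1 (0.326) and PCDHB10 (0.571). They changed with normexp and quantiles for ZNF704 in pcDNA (0.00176) and PCDHB10 (0.0493), and in both value table fits for ALDH3A1 in pcDNA (0.565). ZNF704 and ALDH3A1 were well above background on no pcDNA array and SLC22A13 on no array of at least 1 group, so that no change is read from these 3 values. Of the other values of named genes, 2225 kept direction and side of the threshold, 184 lost the call and 6 gained it.

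Leaving out each array, the counts ranged from 1533 to 2972 between naive lines, 837 to 2193 between TNF-treated lines, 0 to 10 and 2 to 12 for TNF in pcDNA and pcHO1, 3435 to 4797 in the average and 0 to 3 for the interaction. HMOX1 ranged from 0.00737 to 0.928 between naive lines, -0.799 to 0.0633 between TNF-treated lines, -0.513 to 0.441 and -1.18 to -0.457 for TNF in pcDNA and pcHO1, -0.202 to 0.319 in the average and -1.37 to -0.419 for the interaction. The responses to TNF correlated at -0.0932 to 0.128 between lines, and the line differences at 0.647 to 0.767 between treatments.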

Other observations

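The contrasts of replicate numbers and the test of the value table's column were chosen after values were seen. The arrays of replicate 1 differed from those of the other replicates in all 4 groups, and since an experiment is also a slide, cells and slide cannot be told apart. Interferon-stimulated genes were higher in replicate 1, 39 of 43 of them, at a median of 1.92. IFI27 (3.68, adjusted p = 0.00535), IFI44L (3.61) and ISG15 (2.78), induced by interferon and with values on all 12 arrays, were higher. The list passed with camera (adjusted p = 1.33e-20) and fry (adjusted p = 0.00143), with adjusted p = 0.177 with an estimated correlation. Of the 40 genes of G2 and mitosis 32 were lower at a median of -1 (adjusted p = 1.33e-20, and adjusted p = 0.00709 with an estimated correlation), among them the topoisomerase TOP2A by 3.33-fold, the mitotic kinases PLK1 (-1.26) and BUB1 (-1.12) and the cyclin CCNB1 (-0.87). Complement genes (14 of 20 higher, median 0.86, adjusted p = 4.47e-11, adjusted p = 0.0641 with an estimated correlation) and MHC class I genes (12 of 18 higher, 0.86, adjusted p = 7.1e-07, adjusted p = 0.15 with an estimated correlation) were higher.

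Replicate 1 differed from the other replicates in 3390 genes by limma (1501 higher, 1889 lower), replicate 2 in 7 and replicate 3 in 342. Each was set against the other 2 together, so that replicate 1 was part of the reference for replicates 2 and 3. Their counts do not measure how far these replicates differ from each other. The interferon list's deviation from its mean over the 12 arrays was 1.34 in replicate 1 of naive pcDNA, against -1.07 and -1.21 in replicates 2 and 3. In pcDNA with TNF the values were 1.25, -1.22 and -1.44, in naive pcHO1 0.96, -0.22 and -0.21, and in pcHO1 with TNF 1.55, 0.79 and 0.42.

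Of the 12 columns in the deposited value table, 11 had the rank order of their own scanner file. The column of pcHO1 with TNF, replicate 2, correlated at 0.896 with its own file and matched none of the 12. Its rank correlation with pcDNA arrays was 0.921 to 0.963 and with pcHO1 arrays 0.808 to 0.913. A candidate explanation is that this column holds another array of the control line, and the test went that way, as 0.921, the lowest value with a pcDNA array, lay above 0.913, the highest with a pcHO1 array. In that column MXRA5 and BPIFA1, both higher in pcHO1, had no value.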
